A study of Mus musculus with 10 samples.

How the data were processed

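Messenger RNA of mouse blood was sequenced in 10 libraries. Per the labels' protocols, total RNA was extracted with TRIzol and paired-end libraries were prepared with an mRNA kit. The labels call the source whole blood and also carry the words lymphocyte and monocytes, while the series title speaks of peripheral blood mononuclear cells. Which of these describes the sequenced cells is not settled by the labels. The treatment label puts 6 libraries in a burn wound healing group, called burn here, and 4 in a group with the added letters NC, called NC here. The labels used here do not expand NC, and no sample label says which group, if any, received manganese chloride. They also do not say whether the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

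The authors deposited one table of 30984 Ensembl gene identifiers with a read count and an FPKM value for every library. Per the file headers, the count columns hold counts, and their values were whole numbers with a different total in each library. The deposited FPKM values, which scale fragments by gene length and library total, equalled the counts divided by the column total and a whole-number gene length, with a largest relative gap of 5.1e-15. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, its handling of strand and its handling of reads shared between gene copies are not given in the sources used here. Gene symbols came from the deposited table. Positions and gene types came from GENCODE mouse release 21, on the same build, which held 30367 of the 30984 identifiers.

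The design fixed before the data were examined expected FPKM only, with limma on log2(FPKM + 1), and put edgeR in its place if counts were deposited. Counts were present, so edgeR 4.0.16 in R 4.3.3 gave the main result. Genes were kept by filterByExpr with a minimum count of 10, which left 17268 genes for testing. Libraries were scaled by TMM factors, and burn was compared with NC by the quasi-likelihood F test with no covariate. Benjamini-Hochberg adjustment covered all genes tested, with a threshold of 0.05. Differences are log2 values of burn minus NC, and levels are TMM-scaled CPM (counts scaled to the library total) given as mean ± SD. For Itgav, which the series title names, a two-sided exact permutation test over all 210 splits of the libraries was added. The smallest p such a test can give is 0.0048.

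A total of 41 gene lists for blood cell types, pathways, sample quality and admixed tissue were fixed before the data were examined. They were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, on log2 CPM with a prior count of 1. Lists with fewer than 3 tested genes were left out. Adjustment covered the 41 lists. The level of a list in a library is the mean log2 CPM of its members. The same lists were tested with an estimated correlation, with fry and by exact permutation of the list level. Counts of genes past a threshold adjusted over the list alone are given beside those over all genes.

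The rule for named genes was also fixed beforehand. It took Itgav, then up to 10 genes in each direction past the threshold with separated groups, and up to 4 members with the smallest p of each list that passed or held called members. Where fewer than 10 genes passed in a direction, the genes with the smallest unadjusted p filled the 10 and are given as not passing. That last part was read without the expression minimum and the exclusion of predicted genes, pseudogenes and receptor segments that the earlier part carries. This reading, and the prior count of 1 in the list test where exploratory fits had used another value, were chosen after exploratory fits had been seen.

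On simulated counts with the libraries' own means and depths and 50 of the 17268 genes changed at each size, edgeR recovered 24% of genes changed 1.5-fold, 68% at 2-fold, 90% at 3-fold and 90% at 4-fold. It made 8 false calls. The changed genes were drawn only from those above a minimum mean count. Genes were simulated independently and with the same spread in both groups. In the real libraries the median SD within a group was 0.21 log2 units in burn and 0.34 in NC. The recovery rates may therefore be too high for these data. Library totals were 30677206 to 36379663 counts, so counting error was small for most genes, and the spread between libraries set the precision. Replicates were compared by chi-square tests of their counts. The lowest chi-square per degree of freedom was 15.3 within burn and 75.3 within NC, so no pair agreed within sampling noise. This does not tell separate animals from separate preparations of the same RNA.

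In all, 30 alternatives were run for the gene counts and 23 for the lists. They covered the unit and pseudocount, filters, scalings, variance models, DESeq2 1.42.0, covariates for blood composition, the replicate number as a block, and leaving out each library in turn. Added after the data had been seen were limma and camera on log2(FPKM + 1), removal of a gene length trend, and fits without NC 1 and 3 or, for lists, NC 2 and 3.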

Results

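Gene expression was measured in 6 burn and 4 NC libraries of mouse blood, with total counts of 30677206 in NC 3 to 36379663 in burn 4. Haemoglobin genes took 7.17% of the counts in NC 1 and up to 12.8% in NC 2, so red cell RNA was present in every library. Mitochondrial ribosomal RNA took 6.53% in NC 1, the highest share, and 1.30% in NC 4, the lowest. Burn libraries resembled each other more than NC libraries did. The median correlation of log2 CPM was 0.980 within burn, 0.963 within NC and 0.968 between the groups. The median SD of a gene within its group was 0.21 log2 units in burn and 0.34 in NC. The first principal component held 25.8% of the variance and the second 22.5%. NC 1 and NC 3 lay at opposite ends of the second, and burn 1 lay among the NC libraries on the first.

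**Figure D1:**
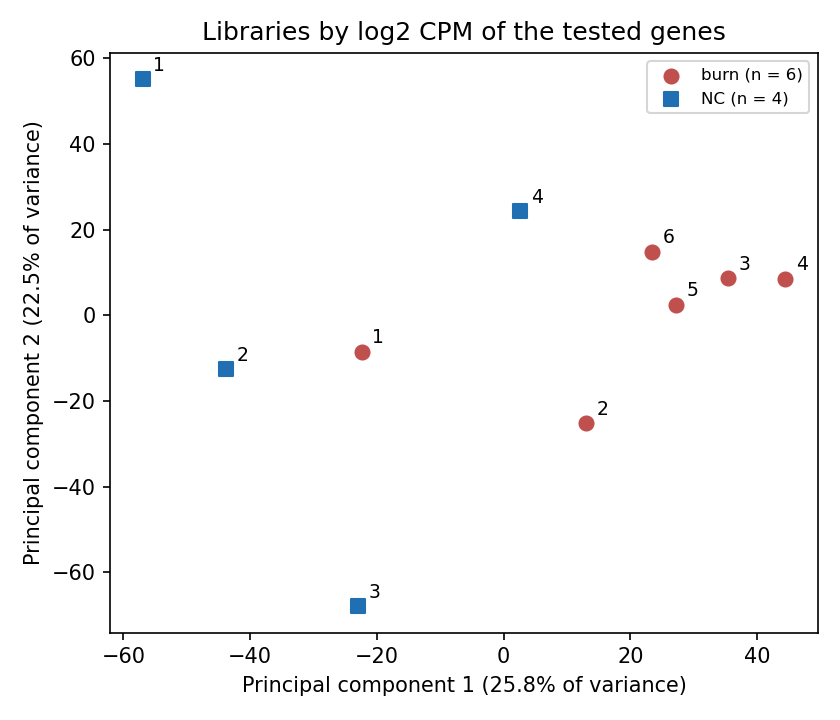
Position of each library on the first 2 principal components of log2 CPM, with the share of variance on each axis and replicate numbers beside the points (burn, 6 circles; NC, 4 squares). Burn 1 sits at -22.4 on the first component, near NC 3 at -22.9, while NC 1 at 55.1 and NC 3 at -67.9 mark the ends of the second.

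The series title names Itgav, the gene of the alpha-v integrin subunit, which pairs with several beta subunits to bind matrix proteins and latent TGF-beta. It was expressed in all libraries, and the groups differed by less than the spread between libraries. Itgav (ENSMUSG00000027087; mm10 chromosome 2, 83724397 to 83806916, plus strand, protein coding) stood at 50.02 ± 5.20 CPM in burn (SD, n = 6) and 45.6 ± 6.4 CPM in NC (SD, n = 4). The deposited FPKM values were 4.72 ± 0.56 and 4.17 ± 0.70. The log2 difference of burn minus NC was 0.13 (SE 0.11, 95% interval -0.10 to 0.36), and edgeR gave an adjusted p of 0.66. The exact permutation p was 0.262 on log2 CPM and 0.195 on log2(FPKM + 1). Without NC 3 the log2 difference was 0.02.

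The comparison of burn with NC asked which genes of the blood transcriptome differed between the treatment groups. No gene passed the threshold in either direction. Of 17268 genes tested with edgeR, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.393. At an unadjusted p under 0.05 there were 1943 genes, 734 with higher and 1209 with lower values in burn, against 863 expected with no difference. DESeq2 on the same counts called 85 genes, 15 higher and 70 lower. Groups did not overlap for 350 genes, or 2.03%, where chance gives 0.952%. Without burn 1, edgeR called 10 genes, all lower in burn. Without NC 4 it called 2 lower genes, Klrk1 and Oaz2. Without NC 1 the genes at an unadjusted p under 0.05 numbered 1260.

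The genes with the smallest p among those with lower values in burn included receptors, stress genes and matrix genes, none of which passed in edgeR. Il18rap, a subunit of the interleukin-18 receptor (chromosome 1, 40515362 to 40551705), stood at 49.9 ± 2.3 CPM in burn and 90.8 ± 24.03 CPM in NC, a log2 difference of -0.86 (SE 0.14). Its edgeR adjusted p was 0.393 and its DESeq2 adjusted p 0.00051. Gadd45a, a gene induced by DNA damage and other stress (chromosome 6, 67035096 to 67037457), stood at 27.0 ± 3.0 and 37.8 ± 2.6 CPM. Oaz2, an antizyme of polyamine synthesis, stood at 54.1 ± 2.1 and 78.5 ± 15.0 CPM. Soat2, a cholesterol-esterifying enzyme, stood at 3.34 ± 0.32 and 7.67 ± 3.24 CPM. Cd209a, a C-type lectin of dendritic cells, stood at 1.28 ± 0.26 and 3.08 ± 1.14 CPM. The matrix genes Aspn and Col15a1 were rare. Aspn had 1 to 12 counts in a burn library and 18 to 44 in an NC library, and Col15a1 13 to 22 and 29 to 59. Ftl1, the ferritin light chain (chromosome 7, 45457944 to 45459884), stood at 214 ± 18 and 301 ± 29 CPM, with a log2 difference of -0.50 (SE 0.09). Its near-identical copy Ftl1-ps1 differed by -0.52. Reads of the pair may be split by the counting, so their separate values are uncertain. The same holds for the inducible Hsp70 gene Hspa1b, at 14.0 ± 3.2 and 25.0 ± 4.2 CPM, and its copy Hspa1a.

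The genes with the smallest p among those with higher values in burn did not pass in edgeR either. Patj, a scaffold protein of cell polarity complexes (chromosome 4, 98395785 to 98719603), stood at 28.2 ± 2.5 CPM in burn and 20.3 ± 1.5 CPM in NC, a log2 difference of 0.48 (SE 0.09). Il9r, the interleukin-9 receptor (chromosome 11, 32187541 to 32200279), stood at 26.0 ± 4.7 and 15.0 ± 3.1 CPM. Hs3st1, a heparan sulfate sulfotransferase (chromosome 5, 39613935 to 39755475), stood at 8.66 ± 0.96 and 5.35 ± 0.76 CPM. Sesn1, a stress-induced sestrin, stood at 173 ± 8 and 136 ± 11 CPM, and Nrip1, a nuclear receptor corepressor, at 133 ± 11 and 105 ± 8 CPM. Bcl2l13, a BCL2 family member, differed by a log2 value of 0.29, and Cd1d1, which presents lipids to natural killer T cells, by 0.27. The T cell receptor segment Traj19 (chromosome 14, 54200386 to 54200446) had 15 to 19 counts in a burn library and 2 to 6 in an NC library. The segment Trav7n-6 had 0 to 42 counts in a burn library and 0 to 2 in an NC library, and the non-coding RNA Gm26685 14 to 24 and 4 to 10. Of these 20 genes, 18 passed in DESeq2, and the exceptions were Bcl2l13 and Gm26685.

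**Figure D2:**
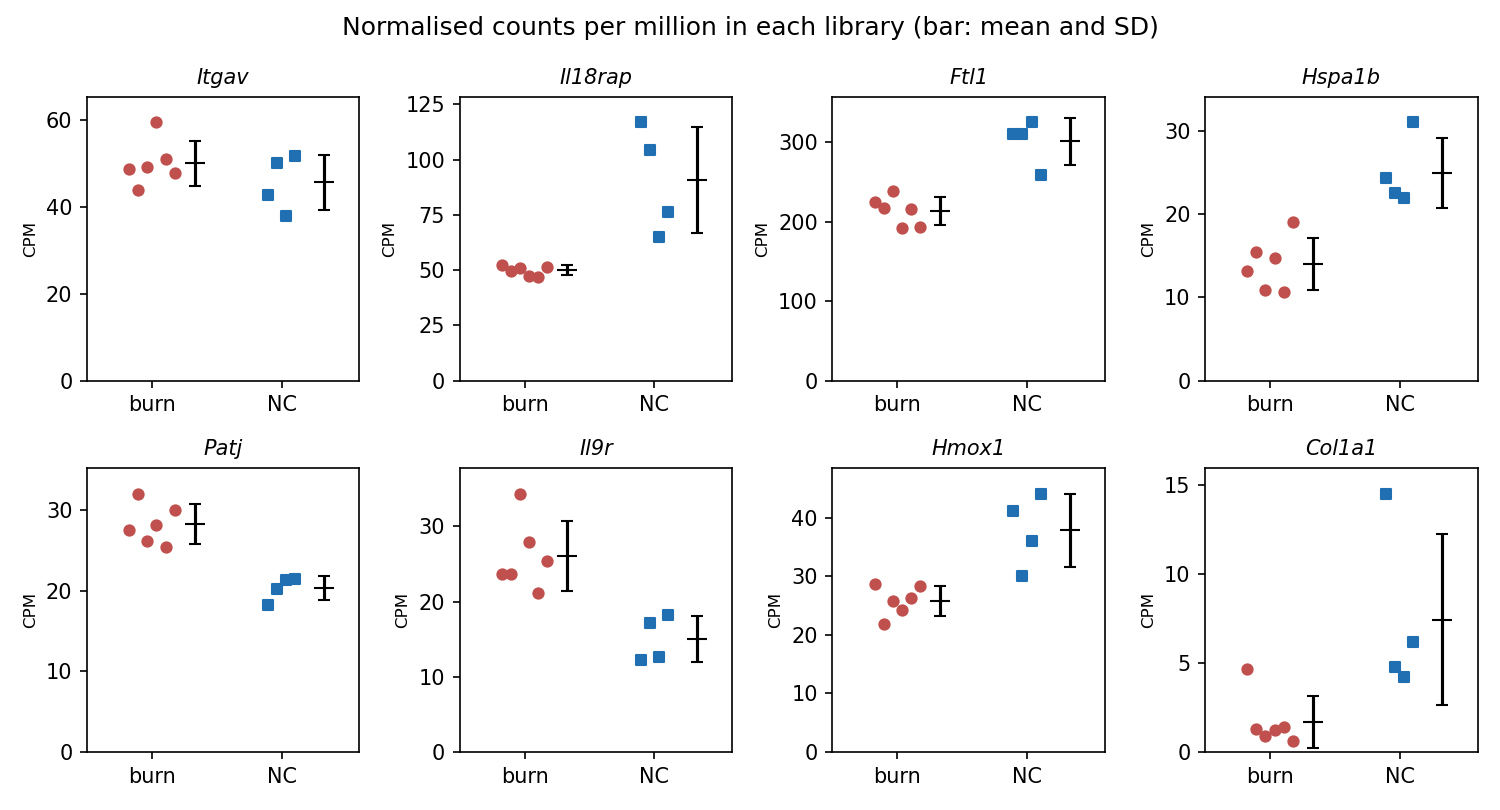
TMM-scaled CPM of 8 genes in each library (burn, 6 circles; NC, 4 squares), with bars for the mean and SD of each group and axes from 0. The groups overlap for Itgav and Col1a1, while every NC library lies above every burn library for Il18rap, from 65.2 CPM in NC 3 to 117 CPM in NC 1.

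Of the 41 gene lists, 15 passed in camera with the preset correlation, 3 higher and 12 lower in burn. With an estimated correlation 0 passed, and 5 reached an unadjusted p under 0.05. In fry 1 list passed, the dendritic cell list. Over the lists taken alone, 23 genes had an adjusted p under 0.05 in edgeR, against 0 over all genes.

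Markers of natural killer and cytotoxic lymphocytes were lower in burn for 17 of 17 members, with a median log2 difference of -0.58. The camera adjusted p was 1.2e-06, and adjusted p = 0.52 with an estimated correlation. Klrk1, the activating receptor NKG2D, stood at 30.0 ± 2.9 CPM in burn and 56.6 ± 24.1 in NC. Eomes, a transcription factor of cytotoxic cells, stood at 16.4 ± 2.4 and 30.2 ± 12.5 CPM, and Tbx21, which encodes T-bet, at 8.72 ± 1.28 and 15.9 ± 7.2 CPM. Adjusted over the list alone, 5 members passed: Klrk1, Eomes, Tbx21, Klre1 and Fasl. NC libraries 2 and 3 carried the highest levels, and without both the camera adjusted p was 0.98. The difference in list level, -0.50 with all libraries, was -0.79 without NC 4.

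B cell and antigen presentation genes had higher values in burn. All 18 B cell markers did so, with a median of 0.30 and a camera adjusted p of 1.4e-05, and adjusted p = 0.52 with an estimated correlation. Pou2af1, a B cell coactivator, stood at 223 ± 37 CPM in burn and 148 ± 34 in NC, and Fcer2a, which encodes CD23, at 216 ± 40 and 148 ± 44. Without both NC 2 and 3 the B cell list had a camera adjusted p of 0.13. All 11 MHC class II genes were higher, with a median of 0.36, a camera adjusted p of 7.3e-05 and adjusted p = 0.52 with an estimated correlation. Burn 2 and 4 were the highest and burn 1 and 6 the lowest burn libraries on both lists. H2-Ob, a modulator of peptide loading, stood at 442 ± 56 and 327 ± 68 CPM. Adjusted over the list alone, 0 members of either list passed. Plasma cell genes went the other way, with 9 of 12 lower. Their camera adjusted p was 0.020, and adjusted p = 0.55 with an estimated correlation. Adjusted over the list alone 2 passed, Igha at 110 ± 29 and 300 ± 260 CPM and Jchain at 30.9 ± 8.8 and 77.9 ± 61.3 CPM. NC 3 had the highest values, 663 CPM of Igha and 160 of Jchain. The plasma cell call was lost without burn 1 (camera adjusted p 0.081), NC 2 (0.12) or NC 3 (0.31). NC 2 and 3 were the highest libraries on the cytotoxic list too. The difference in plasma cell level, -0.41 with all libraries, was -0.62 without NC 1 and -0.23 without NC 3. Without both NC 2 and 3 it was 0.10, with a camera adjusted p of 0.82.

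Markers of connective tissue, epithelium and vessels, fixed as signs of admixed tissue, were lower in burn for 9 of 10 measured members, of 14 listed. In camera the adjusted p was 1.9e-05, and adjusted p = 0.30 with an estimated correlation. The mean list level was -0.02 ± 0.49 log2 CPM in burn and 1.18 ± 0.18 in NC. The collagen genes Col3a1, Col1a1 and Col1a2 and the matrix proteoglycan Lum passed adjusted over the list alone. Col3a1 stood at 2.09 ± 3.27 and 13.5 ± 5.3 CPM, and Col1a1 at 1.68 ± 1.48 and 7.42 ± 4.8 CPM. Burn 1, with 8.73 CPM of Col3a1, was inside the range of the NC libraries, where NC 3 had the lowest value of 8.46 CPM. Among the muscle and liver markers, Ckm alone passed over its list, at 1.84 ± 0.94 CPM in burn and 0.44 ± 0.27 in NC.

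Platelet genes were lower in burn for 19 of 19 measured members, of 20 listed, with a median of -0.72. The camera adjusted p was 1.4e-05, and adjusted p = 0.64 with an estimated correlation. The quality list of replication histones, whose mRNAs lack poly(A) tails, moved with platelet genes. NC 1 was the highest and burn 4 the lowest library on both, at 1.47 and -0.78 from the mean for histones and 1.39 and -0.90 for platelets. Nrgn stood at 660 ± 152 CPM in burn and 1300.4 ± 783 in NC. Without NC 1, the library with the highest share of mitochondrial ribosomal RNA, the platelet list had a camera adjusted p of 0.075, and without both NC 1 and 3 one of 0.53. The difference in platelet level, -0.54 with all libraries, was -0.22 without NC 1 and -0.87 without NC 4. Mature neutrophil genes were lower for 24 of 24, with a median of -0.93, a camera adjusted p of 0.0020 and adjusted p = 0.79 with an estimated correlation. Clec4d, a C-type lectin, stood at 30.8 ± 3.9 and 81.5 ± 62.7 CPM, with 146 CPM in NC 1 and 124 in NC 4. The neutrophil call was lost without NC 1 (camera adjusted p 0.94), NC 4 (0.23) or both NC 1 and 3 (0.40). The difference in neutrophil level, -0.53 with all libraries, was -0.07 without NC 1, -1.07 without NC 2, -0.88 without NC 3 and -0.21 without NC 4. Adjusted over the list alone, 0 platelet and 0 neutrophil genes passed. Ribosomal protein genes were higher for 49 of 50, with a median of 0.17 and a camera adjusted p of 1.9e-05, and adjusted p = 0.79 with an estimated correlation. The ribosomal call was lost without NC 1 (camera adjusted p 0.32), and 0 members passed over the list alone. The difference in ribosomal level, 0.23 with all libraries, was 0.04 without NC 1, 0.15 without burn 2 and 0.42 without NC 3 (camera adjusted p 1.2e-26). NC 1 was the lowest and NC 3 the highest library on the T cell list too, at -0.42 and 0.45 from the mean against -0.65 and 0.51 for ribosomal genes. The level of short genes moved along as well. The median deviation of the shortest of 5 length bins was highest in NC 3 (0.19) and burn 2 (0.10) and lowest in NC 1 (-0.09), as for ribosomal genes. With a gene length trend removed the ribosomal list had a camera adjusted p of 0.00099.

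Genes of the NRF2 response and antioxidant defence were lower in burn for 21 of 27, with a median of -0.23. In camera the adjusted p was 7.3e-05, and adjusted p = 0.30 with an estimated correlation. Adjusted over the list alone 3 members passed. Hmox1, haem oxygenase 1, stood at 25.9 ± 2.6 and 37.9 ± 6.2 CPM, and the ferritin heavy chain Fth1 at 1656 ± 251 and 2575 ± 626 CPM, beside Ftl1. The separate list of manganese and iron handling had 5 higher and 7 lower members and a camera adjusted p of 0.91. The NRF2 list kept its call in all 10 fits that left out 1 library, with the preset correlation. So did the cytotoxic, B cell, MHC class II, connective tissue, alpha-v integrin, eosinophil and basophil, and glycolysis and hypoxia lists. Heat shock genes were lower for 9 of 12, with a camera adjusted p of 0.0034 and adjusted p = 0.52 with an estimated correlation. Hspa1b, Hspa1a and the cochaperone Bag3 passed over the list alone, and the call was lost without NC 3 (camera adjusted p 0.11). Glycolysis and hypoxia genes were lower for 19 of 23, with a camera adjusted p of 0.0034 and adjusted p = 0.35 with an estimated correlation. Its 4 members with the smallest p included the glucose transporters Slc2a1 and Slc2a3, and 0 passed over the list alone. TPM scaling ended that call, with a camera adjusted p of 0.055, as did leaving out both NC 1 and 3 (0.17). The difference in level, -0.19 with all libraries, was -0.12 without NC 1 and -0.29 without NC 2. Neutrophil genes moved with this list. NC 1 and 4 were the highest libraries on it, at 0.40 and 0.14 from the mean, and the highest on the neutrophil list, at 1.81 and 1.29. Burn 5 and 6 were the lowest burn libraries on both.

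The alpha-v integrin partner list holds alpha-v integrin, its beta partners and TGF-beta ligands. In it, 12 of 16 measured members were lower in burn, with a median of -0.47. The camera adjusted p was 0.0020, and adjusted p = 0.35 with an estimated correlation. Adjusted over the list alone 2 passed, the beta subunit Itgb5 and Ltbp2, of the latent TGF-beta binding protein family. Itgb5 stood at 82.8 ± 14.9 CPM in burn and 180 ± 107 in NC. Ltbp2 stood at 3.18 ± 1.30 and 10.6 ± 9.0 CPM, with 23.8, 8.94, 6.03 and 3.73 CPM in NC 1 to 4. Platelet genes moved with this list. NC 1 was highest and burn 4 lowest on both, and NC 1 to 4 had 333, 155, 151 and 81.2 CPM of Itgb5 and 2371, 1183, 1159 and 488 CPM of the platelet gene Nrgn. Without both NC 1 and 3 the camera adjusted p was 0.085. Eosinophil and basophil genes were lower for 13 of 16, with a camera adjusted p of 0.0034, adjusted p = 0.30 with an estimated correlation and 0 members past the threshold over the list alone. NC 1 and 4 were the highest on this list as on the neutrophil list, and burn 5 and 6 were the lowest burn libraries on both. Dendritic cell genes were lower for 9 of 12. Cd209a and Clec9a passed over the list alone, while Itgae had a higher value in burn. The camera adjusted p was 0.034, and adjusted p = 0.30 with an estimated correlation. Every burn library lay below every NC library on this list, as on the NRF2 and connective tissue lists. The exact permutation p of those was 0.014 and 0.0095. For the dendritic cell list it was 0.0048, the smallest possible, and 0.195 adjusted over the lists. After that adjustment 0 lists passed the permutation test. Over 41 lists, a single list at the smallest possible p cannot pass, so the adjusted value does not decide. The camera call of the dendritic cell list was lost without burn 1 (adjusted p 0.11), burn 2 (0.059), burn 6 (0.061), NC 3 (0.15) or NC 4 (0.13). Inhibitory and suppressive genes, among them Entpd1 and Tigit, were lower for 16 of 20, with 0 past the threshold over the list alone. In camera the adjusted p was 0.038, and adjusted p = 0.30 with an estimated correlation. Neutrophil genes moved with this list. NC 1 was highest and burn 5 lowest among the burn libraries on both, and NC 1 to 4 had 79.8, 31.6, 29.3 and 87.1 CPM of Entpd1 and 146, 21.3, 34.5 and 124 CPM of the neutrophil gene Clec4d. The call of the suppressive list was lost without burn 1 (adjusted p 0.10), burn 2 (0.066), burn 5 (0.075), NC 1 (0.10), NC 3 (0.094), NC 4 (0.073) or both NC 1 and 3 (0.23). Its difference in level, -0.22 with all libraries, was -0.14 without NC 1 and -0.34 without NC 2.

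**Figure D3:**
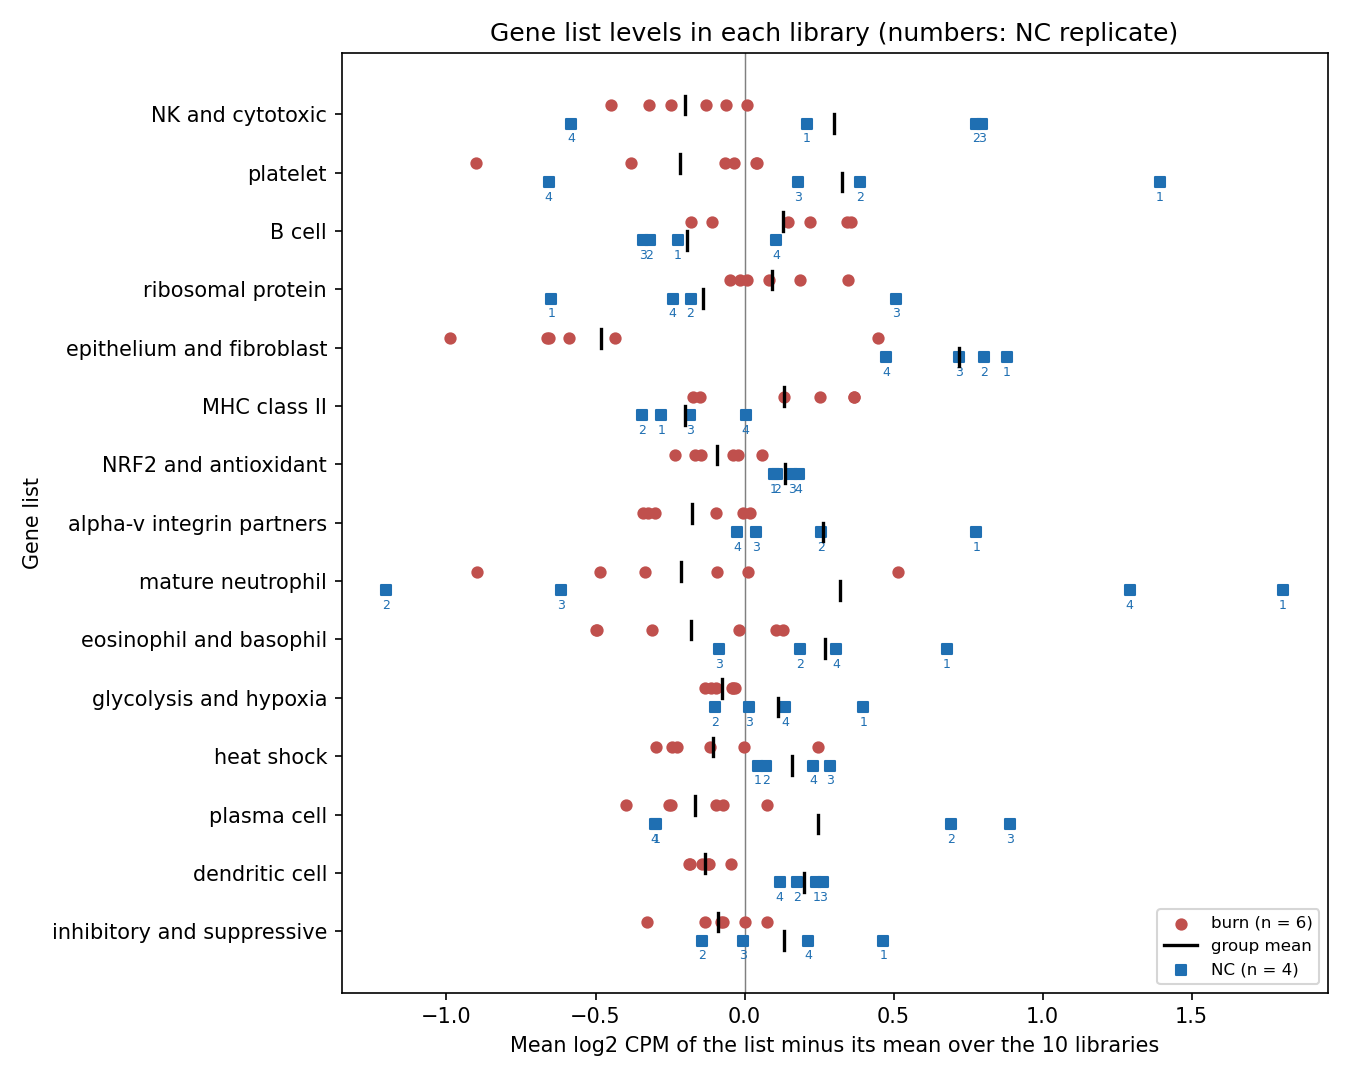
Level of the 15 lists that passed in camera with the preset correlation, as mean log2 CPM of the members minus the mean over the 10 libraries, one point per library (burn, 6 circles; NC, 4 squares with replicate numbers; black bars, group means). NC libraries are spread widely on the neutrophil list. They do not overlap the burn libraries on the dendritic cell, NRF2 and antioxidant, and epithelium and fibroblast lists.

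The remaining lists did not pass in camera. Those of T cells (median log2 difference 0.10), regulatory T cells (0.13), classical monocytes (0.01), nonclassical monocytes (0.01), plasmacytoid dendritic cells (0.10), immature neutrophils (-0.43) and erythroid cells (-0.05) cover other blood cells. Those of type I interferon (-0.06), interferon-gamma (0.06) and cGAS-STING (0.11) genes, inflammatory cytokines (-0.41), leukocyte adhesion (-0.15), NADPH oxidase (0.02), and MHC class I (0.09) cover immune responses. Those of manganese and iron handling (-0.03), metallothioneins (0.12), the cell cycle (-0.05), oxidative phosphorylation (0.06), endoplasmic reticulum stress (0.00), p53 and apoptosis (0.04) and glucocorticoid targets (-0.05) cover metabolism and stress. Ddit4, a glucocorticoid target, passed over its list alone, at 96.6 ± 12.6 CPM in burn and 69.4 ± 11.9 in NC. The quality lists gave -0.11 for immediate early genes, -0.01 for mitochondrially encoded genes, -0.66 for replication histones and -0.33 for sex-linked genes, and the muscle and liver list gave -0.18. For 11 of the lists that did not pass, the median, the mean and the direction of the test differed in sign. Without NC 1 the nonclassical monocyte, immature neutrophil and erythroid lists turned direction and passed, as given below.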

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

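Among 132 pairs of a group and a result, 5 held a library far from the others of its group by Dixon's test, which flags about 1 in 20 groups by chance. In burn, replicate 4 had the highest level of the nonclassical monocyte list, at 6.21 log2 CPM against 5.86 in the next library. Replicate 1 had the highest level of the sex-linked list, at 2.14 against 1.30. Replicate 5 had no Trav7n-6 counts, which gives -5.08 log2 CPM with the prior count, against -1.08 in the next. In NC, replicate 1 had the highest level of the immature neutrophil list, at 4.22 against 2.21. Replicate 4 had the highest Sesn1, at 7.26 log2 CPM against 7.04.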

How the results depend on the processing

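Among 30 alternatives for genes, some added after the data had been seen, counts of calls moved as follows from 0 higher and 0 lower. Genes higher in burn numbered 2 in limma on log2(FPKM + 1) (Traj19 and Snord37), 1 with a pseudocount of 0.1 and 1 with 0.01 (Traj19), 2 after quantile normalisation (Traj19 and Snord37) and 15 in DESeq2. Genes lower in burn numbered 4 with sample quality weights in voom (Col3a1, Il18rap, Nppa and Eln) and 70 in DESeq2. Leaving out 1 library gave 0 to 0 higher and 0 to 10 lower genes. The 10 came without burn 1 (among them Postn, Nppa, Eln, Sparc and Lum), and DESeq2 also called 6 of them. Without NC 4 there were 2 (Klrk1 and Oaz2). Snord37, Nppa, Eln, Postn and Sparc were chosen after their values were seen. Genes at an unadjusted p under 0.05 ranged from 761 to 2842. The 761 came from 7133 genes tested, with FPKM of at least 5, and the 2842 from 17268, without NC 3. Itgav stayed short of the threshold in its 29 alternatives, at -0.05 to 0.24 log2 and adjusted p 0.362 to 0.937, and at 0.02 to 0.20 leaving out 1 library. It has no value where FPKM of at least 5 was required.

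Against 15 of 41 lists in camera with the preset correlation, 0 passed with an estimated correlation, 1 in fry and 2 in its mixed test, and 12 to 19 leaving out 1 library. The estimated correlation between genes was 0.92 for platelet, 0.93 for ribosomal and 0.79 for cytotoxic genes, far above the preset 0.01. It was 0.04 for the NRF2 list and -0.06 for the dendritic cell list. For lists with a high estimate, the preset makes the camera p-values too small. The cause of the other changes was not tested. Without both NC 1 and 3, 3 lists turned direction and passed, by the difference in list level (mean log2 CPM, not the median over genes): nonclassical monocyte from 0.05 to -0.21, immature neutrophil from 0.01, with a test direction of lower, to 0.54 and erythroid from 0.27 to -0.41. Without NC 1 alone the same 3 lists also turned direction and passed. Leaving out 1 library, their level differences ranged from -0.18 (without NC 1) to 0.16, from -0.26 to 0.52 (without NC 1) and from -0.28 (without NC 1) to 0.60. Without both NC 2 and 3 the plasma cell list turned to 0.10, with a camera adjusted p of 0.82. Of 940 list alternatives, 817 kept their side of the threshold, 76 lost a call, 40 gained one and the 7 named here turned direction. In 84 list alternatives without a call the sign changed, as it did in 4 of 2234 single-gene alternatives. TPM scaling moved the median difference of all genes to 0.14, and limma with pseudocounts of 0.1 and 0.01 to 0.11 and 0.12, from 0.02, so higher values there are partly that shift.

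The values show no clear pairing of the samples by replicate number, though matched samples cannot be excluded. The deviations of same-numbered libraries from their group means correlated at -0.05, -0.04, -0.07 and 0.34, and by that measure NC 1 to 4 correlated best with burn 6, 1, 2 and 4. With the replicate number as a block, burn 5 and 6 have no NC library of the same number and add nothing to the comparison. In that fit 0 genes passed, 954 had an unadjusted p under 0.05 and 12 lists passed. The neutrophil, suppressive and dendritic lists then had camera adjusted p of 0.088, 0.11 and 0.055. Rare genes such as Traj19 and Trav7n-6 rest on few counts, and whether depth limits their results was not tested.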

Other observations

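The tests of leaving out NC 1, of leaving out NC 2 and 3, and of splits for adjusted p were chosen after the results were seen. The second connective tissue list and the heart list were written after the first list's result and before their own. Low levels of some long transcripts in NC 3 had also been seen before its correlations were computed.

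Most heart muscle genes had higher values in burn, where connective tissue genes had lower ones. Of 16 measured genes in a heart list, of 18 listed, 14 had higher values in burn, with an exact permutation p of 0.090 for the list level. Nppa, the atrial natriuretic peptide gene, was left out of that list because its lower value in burn had already been seen. With Nppa added the median log2 difference was 0.80 and the exact permutation p 0.167. Myh6, the cardiac myosin heavy chain and the most abundant, stood at 47.3 CPM in burn and 12.4 in NC. Myl2 stood at 10.2 and 3.57 CPM, and Tnni3 at 4.84 and 1.31. The groups overlapped for Myh6, Myl2 and Tnni3. Burn 3 was the highest library for each, at 101.5, 19.0 and 9.0 CPM. Burn 1 was the lowest burn library for each, at 10.3, 2.6 and 0.98 CPM, below NC 3 at 26.8, 6.66 and 1.91. Nppa stood at 0.53 and 4.23 CPM, with 2.14 in burn 1 and 0.11 to 0.33 in the other burn libraries. Col3a1 was likewise highest in burn 1 among the burn libraries. Elastin, Eln, stood at 0.33 and 2.77 CPM. None of these genes passed in edgeR on all libraries, with adjusted p of 0.393 for Myh6, Nppa and Eln. Without burn 1, edgeR called Nppa, Eln and Col3a1 as lower in burn, each at an adjusted p of 0.0016. On all libraries DESeq2 called Nppa (adjusted p 0.012) and Eln (0.0053). Nppa and Eln were chosen after their values were seen.

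The lower connective tissue list in burn was weighed against carried-over tissue. A single library as the source is argued against, since the difference in list level was -1.15 without NC 1 and -1.20 with it. A second connective tissue list, with 24 of 27 genes lower, had a median of -1.12 and an exact permutation p of 0.014. Connective tissue carried into the samples may therefore account for the lower list in burn. Pi16, the most abundant gene of the second list at 36.6 CPM, overlapped between groups. It stood at 64.1, 24.1, 29.9 and 67.9 CPM in NC 1 to 4 and at 25.3 to 37.2 CPM in burn. Heart muscle stays open: the list without Nppa had a median log2 difference of 0.96, opposite in sign but within its spread, while Nppa was lower. A difference in blood sampling between the groups and an effect of the treatment stay open, and the labels used here do not record how blood was drawn.

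The lower cytotoxic and higher B cell lists may reflect different shares of these cells. Members varied together within groups, with a median pairwise correlation of 0.84 for cytotoxic and 0.69 for B cell genes, against 0.13 and 0.18 at the upper end of random lists. The erythroid list did so too, at 0.85 against 0.13, though its camera adjusted p was 0.91. Co-variation was therefore not particular to lists that differed between groups, and it does not tell what set the groups apart. On the scaling of all 10 libraries, the cytotoxic difference was -0.014 without NC 2 and 3 and -0.50 with them. The bound set for NC 2 and 3 as the whole source was 0 or above, so this test did not decide, and a change in cell shares from the treatment stays untested.

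NC 3 differed from the other libraries by gene length and base composition. Its deviation correlated with gene length across genes at a Spearman rho of -0.23, the lowest of the 10 libraries, and with transcript GC content at 0.22, the largest in size. Genes are not independent replicates. Either property may be the source, and the tests do not separate them. No biological explanation was tested for a single library.

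The count of genes past the adjusted threshold was 0, which all 100 of the 100 splits drawn reach by construction, so the splits say nothing about it. The highest other split, which exchanges burn 1 and NC 4, called 149 genes. What sets these libraries apart, including a wrong label or another way of drawing blood, was not tested, and that doubt bears on every value of burn against NC. For unadjusted p, 4 of 100 splits reached 1943 genes, the real one included. The other 3 gave 2391, 2894 and 2954, above the real count, and the median was 759. The 4 splits fall under the limit of 5 set beforehand. Since only 100 of the 210 splits were drawn and 3 others exceeded the real count, chance is not firmly excluded. Leaving out 1 library gave counts from 1260 (without NC 1) to 2842 (without NC 3). For lists with the preset correlation, 20 of 100 splits reached the real 15, with a highest other of 20 and a median of 12, so chance cannot be excluded.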
